A study of Mus musculus with 9 samples.

How the data were processed

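DNA methylation was measured by reduced representation bisulfite sequencing, in which genomic DNA is cut with MspI (an enzyme whose sites hold a CpG) and treated with bisulfite, so that unmethylated cytosines are read as thymine. Per the labels' protocols, the cells came from spleens of female C57Bl/6J mice aged 10 weeks, adaptors of 2 kinds were used, libraries were amplified by PCR, and single-end reads were taken on a HiSeq instrument. Which library received which adaptor is not given in the sources used here. Per the submitters' processing notes, reads were handled with Bismark and Bowtie2 against mouse build mm9; versions are not given in the sources used here. The authors deposited, for 911004 CpGs, the counts of methylated and unmethylated reads of each library, with calls from both strands summed per the file headers. Beside the counts, the deposited table holds the methylation level as a fraction, which equals methylated reads divided by all reads at every CpG to within rounding. Every CpG of that table had a summed coverage of at least 10 in each group. The deposited table also gives the closest gene by transcription start site, the distance to it and a class (promoter, exon, intron or intergenic, with promoters from 2500 bp upstream to 500 bp downstream). Of all CpGs 10.3% carried no gene symbol. The authors further deposited lists of differential CpGs for plasmablasts and for plasma cells against naive B cells; per the file headers these passed a false discovery rate of 0.01, and the tool is not given in the sources used here.

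The lists of genes, the thresholds and the tests were set before the data were examined, as were the alternatives except those said to be chosen after seeing the data. Samples were grouped by GEO's labels into naive B cells, plasmablasts and plasma cells, 3 libraries each. The labels do not say which animals the libraries came from, so p-values reflect only the spread between these libraries, which may be technical. For single CpGs that spread is pooled over all CpGs. Replicate libraries of a group correlated at 0.956 to 0.986 over CpG levels and held identical counts at no more than 1.29% of CpGs, so each was counted as 1 sample. Total read counts over CpGs ran from 16037172 to 29948088 per library. PCR reads without molecular identifiers are not independent molecules, and limits drawn from read counts cover counting error only.

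The 356320 CpGs (39.1% of those deposited) with at least 10 reads in each of the 9 libraries were tested. The median coverage of these CpGs was 24 to 36 reads per library. Each CpG was fitted with a quasi-binomial logistic model with 1 level per group over all 9 libraries, written in R 4.3.3 with the data.table package, version 1.17.8. The Pearson dispersion was moderated across CpGs with limma 3.58.1 and never taken below 1. It came to 1.27 for all CpGs. A single CpG's own spread between libraries therefore does not enter its p-value, which follows its levels and its read depth. Contrasts were tested with an F test from the deviance and adjusted by Benjamini-Hochberg. A CpG was called at an adjusted p under 0.01 and a difference of pooled levels of at least 20 percentage points. Reads were also summed over the CpGs assigned to a gene, here called a gene locus, where at least 5 were tested; 14220 genes were tested with the same model and called at an adjusted p under 0.01 and a difference of at least 5 points. The same was done for 7117 genes with CpGs within 1000 bp of the start site. Levels printed are unweighted means of the libraries' levels, and differences that were tested are of pooled reads. Mean levels per library over CpG classes were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1.

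The 14 gene lists were tested with limma's camera (preset correlation 0.01) on log2 ratios of methylated to unmethylated reads with 1 added to each, adjusted over all lists and the 3 contrasts, with a list called at an adjusted p under 0.05. Camera asks whether a list moved more or less than the other genes. With an estimated correlation no list was called in any contrast. The count of list genes with at least 1 lower CpG was set against 10000 random lists matched on the number of tested CpGs (one-sided, toward more genes). The lists were the plasma cell program, mature B cell identity, the unfolded protein response and secretion, proliferation, the DNA methylation machinery, the response through TLR4 and NF-kB, homing and adhesion receptors, markers of T cells, NK cells, myeloid cells and erythroid and stem cells, imprinted genes, germline genes, and Hox clusters with Polycomb developmental genes. Genes named in the text follow a fixed rule: the 10 with most CpGs lower in plasma cells than naive B cells, the 5 with most CpGs higher there, the 5 with most CpGs called between plasmablasts and plasma cells, 2 to 4 members of each list with most called CpGs, and a short set always named where tested (Prdm1, Irf4, Xbp1, Sdc1, Jchain, Tnfrsf17, Pax5, Bach2, Ebf1, Ciita, Cr2 and Dnmt1 among them). Jchain and Tnfrsf17 had fewer than 5 tested CpGs, and some genes that the rule selects are not reported here. Clusters are runs of at least 3 CpGs called the same way with at most 300 bp between neighbours, and the 5 with most CpGs lower in plasma cells are named. Positions are 1-based on mm9.

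After seeing the data, libraries were placed in 2 sets by their level at 78187 CpGs with a mean under 5%, with the border at 2%. Naive B cells 1 and all 3 plasma cell libraries lay in the low set, and naive B cells 2 and 3 with all 3 plasmablast libraries in the high set. The set was used as a model term, each library's level at these CpGs was subtracted, and comparisons were repeated within a set. For CpGs and gene loci this term, like the replicate block below, entered the p-value only. The direction and the minimum difference were those of the unadjusted pooled levels. Other alternatives were higher coverage minimums, other thresholds, Fisher's exact test on pooled counts (Numba 0.67.0 and SciPy 1.17.1), edgeR 4.0.16 and limma on log2 ratios, the replicate number as a block, and each library left out in turn. Tables and plots were also handled with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

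The model was tested on simulated data with the real CpGs and coverages, for plasma cells against naive B cells. The simulated spread was derived from the model's own dispersion, with 1 setting for all CpGs and no library effect. Its false calls therefore do not bound those in the real data, where spread may differ between CpGs and libraries fall in sets. Among 356320 CpGs, changes of 20, 30 and 40 points were simulated at 67, 67 and 66 CpGs, of which 8.96%, 40.3% and 71.2% were called, with 1 false call. Without the minimum difference 66 CpGs were falsely called. Their median difference was 4.73 points and their median coverage summed over libraries 17575.5, against 276 for all CpGs, so counts without a minimum difference are too high at very deep CpGs. At the same sizes edgeR called 0%, 22.4% and 37.9%, limma 0%, 0% and 7.58%, and the model with the library set as a term 1.49%, 7.46% and 27.3%. Among 14220 simulated gene loci, changes of 10 and 20 points were called at 30% and 81%, with 0 false calls. A shift of 10 points in 1 list was called at an adjusted p of 2.47e-31, with 0 other lists called.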

Results

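CpG methylation was profiled in 9 libraries of sorted mouse spleen cells, 3 from each of 3 stages of the B cell lineage. Naive B cells (B220+ CD43-) came from untreated mice. Plasmablasts, the dividing stage before plasma cells (CD138+ with intermediate B220), and plasma cells, the end stage of the lineage (CD138+ with low B220), were induced with the bacterial lipopolysaccharide LPS and taken on day 3. Read counts over CpGs totalled 29948088, 20252680 and 16037172 in naive B cells 1 to 3, 17366816, 19304010 and 17442738 in plasmablasts 1 to 3, and 25239966, 23168926 and 26202053 in plasma cells 1 to 3. Naive B cells 2 and 3 had no read at 69627 and 82986 of the 911004 CpGs, against 119 to 4628 in the other libraries. At 356320 CpGs every library had at least 10 reads, and these CpGs are compared.

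The libraries also differed at CpGs that carried almost no methylation. Over 78187 CpGs with a mean level under 5%, the level was 0.749% in naive B cells 1 but 3.13% and 2.63% in naive B cells 2 and 3. It was 2.70%, 6.11% and 2.08% in the plasmablast libraries and 1.13%, 1.16% and 1.07% in the plasma cell libraries. Over 18 CpGs of the mitochondrial genome the level was 0.332% in naive B cells 1 and between 0.896% and 1.05% in plasma cells, while the other 5 libraries lay between 2.77% and 7.18%. The low set (naive B cells 1 and the plasma cells) and the high set (naive B cells 2 and 3 and the plasmablasts) were therefore also compared within themselves.

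**Figure D1:**
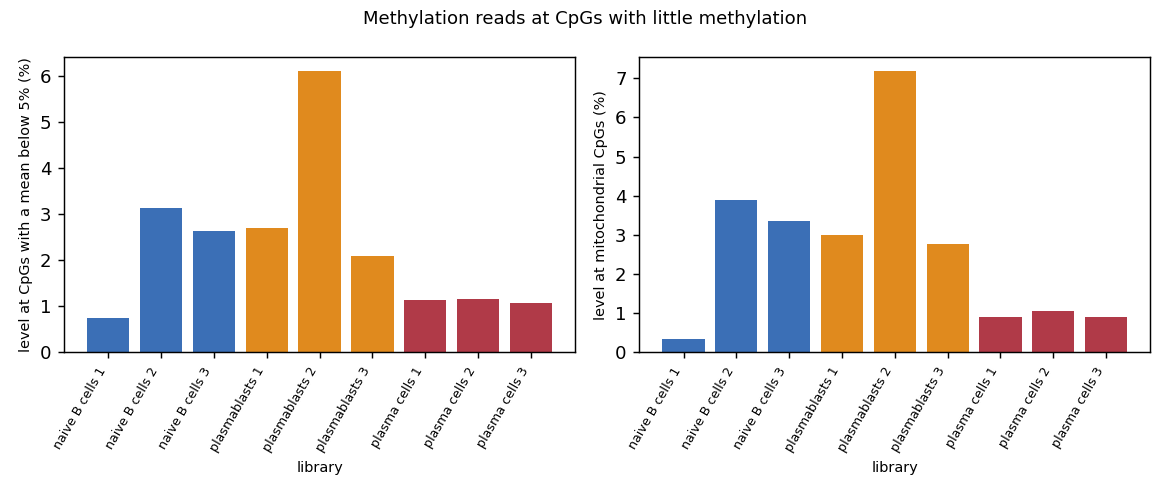
Methylation level (%, y axis, from 0) of each library at 78187 CpGs with a mean level under 5% (left) and at 18 mitochondrial CpGs (right), 1 bar per library, coloured by group. Naive B cells 1 sits with the plasma cells on both measures, and plasmablasts 2 is highest at 6.11% and 7.18%.

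The first question was which CpGs differ between naive B cells and plasmablasts. Plasmablasts carried less methylation, and nearly all changes were losses at CpGs with a high level in naive B cells. Of the 356320 CpGs 37368 (10.5%) fell and 225 rose. CpGs above 80% in naive B cells could not rise by the minimum difference, and those at 80% or more made up 57.5% of the tested CpGs. The CpGs that fell averaged 90.5% ± 0.765 in naive B cells and 61.8% ± 1.02 in plasmablasts (SD, n = 3). Il10, the gene of an anti-inflammatory cytokine, fell from 64.4% ± 2.33 to 22.7% ± 5.77 over 19 CpGs, and Tet2, which encodes an enzyme that oxidises methylated cytosine, fell from 87.9% ± 0.822 to 65.8% ± 2.90 over 26 CpGs. Pax5, the transcription factor that holds B cell identity, fell from 64.6% ± 2.43 to 49.9% ± 1.93 over 94 CpGs.

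The mean level over all CpGs was 62.4% ± 1.23 in naive B cells and 54.8% ± 1.16 in plasmablasts, a difference of -7.62 points, lower in each of the 3 plasmablast libraries than in any naive B library (exact two-sided permutation p = 0.1, the smallest this design allows). Within the high set the difference was -8.32 points. Intergenic CpGs stood at 78.6% ± 1.15 and 67.7% ± 0.907, and introns at 69.5% ± 1.18 and 60.7% ± 1.06. Promoter CpGs stood at 22.0% ± 1.54 and 20.7% ± 1.96 (exact permutation p = 0.3), and CpGs within 1000 bp of a start site at 15.8% ± 1.55 and 15.7% ± 2.04 (exact permutation p = 1.0), differences within the spread of the libraries. With the library background subtracted, chosen after seeing the data, these differences went from -1.27 to -2.26 points and from -0.18 to -1.20. Within the high set promoters differed by -2.15 points. The level fell at 15.0% of intergenic, 12% of intronic, 4.72% of exonic and 3.17% of promoter CpGs. With promoter CpGs at 22.0% in naive B cells, many could not fall by the minimum difference. These shares therefore do not separate class from starting level.

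**Figure D2:**
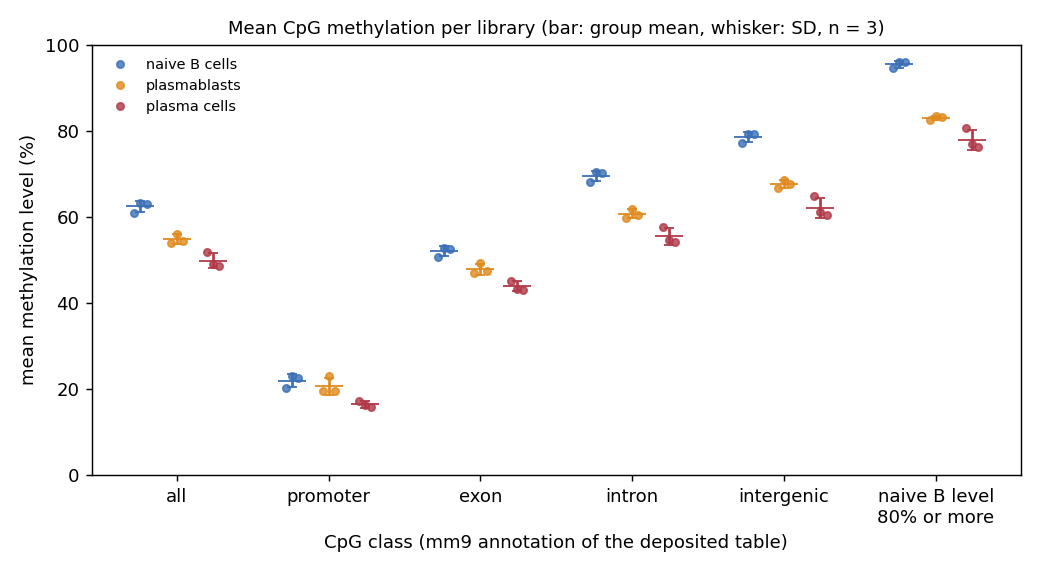
Mean methylation level (%, y axis) over CpG classes of the mm9 annotation and over CpGs at 80% or more in naive B cells, with 1 point per library, a bar at the group mean and a whisker of 1 SD (n = 3). In introns, intergenic CpGs and CpGs of high naive level the 3 groups do not overlap, while in promoters plasmablasts (19.5% to 23.0%) overlap naive B cells (20.2% to 23.1%).

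Among gene loci, 3707 of 14220 fell in plasmablasts and 1 rose, with a median difference over all loci of -7.42 points. The locus that rose was Pbx2, a homeobox transcription factor gene, at 30.6% ± 5.69 in naive B cells and 48.1% ± 2.10 in plasmablasts (adjusted p = 0.0052); it was named after its value was seen. Within 1000 bp of start sites 50 of 7117 genes fell, among them Traf1, a signalling adaptor of TNF receptors, from 40% ± 5.54 to 13.5% ± 3.86 over 10 CpGs (adjusted p = 0.000136). No gene rose there by the quasi-binomial test with limma's dispersion (0 of 7117), but the median difference was 1.58 points, and at an unadjusted p under 0.05 more genes were higher (604) than lower (454). Plasmablasts also stood higher at CpGs with a mean under 5% (3.63% ± 2.17 against 2.17% ± 1.26), so the upward shift need not be methylation of these genes. The count of loci depended on single libraries: it was 1816 and 2066 without naive B cells 2 or 3, 1891, 2067 and 2115 without plasmablasts 1, 2 or 3, and 7998 with unweighted means of CpG levels per gene in limma, chosen after seeing the data. CpGs that rose numbered 104 without naive B cells 1 and 135 without plasmablasts 2. More than 1 locus rose without naive B cells 1 and with the library set as a term, the latter chosen after seeing the data.

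The second question was how far plasma cells had moved from naive B cells. Plasma cells carried the lowest methylation of the 3 groups: 80488 CpGs (22.6%) fell and 158 rose. The CpGs that fell averaged 89.0% ± 1.12 in naive B cells, 69.0% ± 1.05 in plasmablasts and 57.8% ± 3.81 in plasma cells (SD, n = 3). Irf4, a transcription factor needed for plasma cell formation, fell from 35.6% ± 12 to 2.94% ± 1.96 over 5 CpGs, and Prdm1, which encodes the plasma cell regulator Blimp-1, fell from 67.9% ± 2.12 to 48.6% ± 7.21 over 40 CpGs. Ciita, the activator of MHC class II genes that plasma cells switch off, fell from 93.4% ± 2.18 to 65.7% ± 2.68 over 12 CpGs.

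The mean over all CpGs was 49.8% ± 1.77 in plasma cells, a difference of -12.6 points from naive B cells (exact two-sided permutation p = 0.1, the smallest possible). Within the low set, which holds 1 naive B library, the difference was -11.2 points. Intergenic CpGs stood at 62.1% ± 2.32 in plasma cells, introns at 55.5% ± 1.95, exons at 43.8% ± 1.17 and promoters at 16.5% ± 0.750. CpGs at 80% or more in naive B cells averaged 95.4% ± 0.821 there and 77.9% ± 2.39 in plasma cells. The share of CpGs that fell was 31.7% in intergenic sequence, 25.5% in introns, 11.3% in exons and 7.82% in promoters, so that intergenic CpGs made up 47.8% of the losses and 34.0% of the tested CpGs. Beyond 100 kb from a start site 34.4% of CpGs fell, and within 1 kb 4.89%. Mean naive levels there were 88.1% and 15.8%, so many CpGs near start sites could not fall by the minimum difference. The shares by class and distance therefore do not separate position from starting level. Among CpGs nearly full in naive B cells (means of 97.8% within 1 kb and 97.9% beyond 10 kb), 21.6% and 26.2% fell. The X chromosome stood at 70.7% ± 1.48 in naive B cells and 55.5% ± 3.14 in plasma cells.

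Losses were spread over long stretches of single loci. As 22.6% of all tested CpGs fell, a ranking by count favours genes with many tested CpGs. The genes with most fallen CpGs were Prdm16, a zinc finger regulator of transcription (73 of 227 CpGs), Casz1 (72 of 242), Sept9 (67 of 210), Sdk1, a cell adhesion gene (65 of 144), Camta1 (59 of 220), Nav2 (58 of 170), Bcl11b, a T cell transcription factor (56 of 267), Kazn (54 of 186), Tshz2 (54 of 215) and Cdh23, a cadherin (52 of 145). Each of these loci fell: Prdm16 from 74.0% ± 0.669 to 53.4% ± 5.54 (adjusted p = 3.51e-05), Sdk1 from 85.3% ± 2.65 to 61.9% ± 3.70 (adjusted p = 2.09e-05), and the other 8 at adjusted p between 1.5e-05 and 2e-04. Locus levels weight CpGs by their reads, and reads within 1 kb of start sites made up 22.7% to 29.8% of those in naive B libraries and 29.3% to 38.4% in plasma cell libraries, so part of a locus difference may lie in which CpGs hold the reads. Where unweighted means of CpG levels, chosen after seeing the data, changed a printed difference by more than 1.5 times, they are given beside it. In all, 9638 of 14220 loci fell and 0 rose by the quasi-binomial test with limma's dispersion, and at an unadjusted p under 0.05 the counts were 11863 and 0. With unweighted means in limma, chosen after seeing the data, 2 rose.

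Mature B cell identity genes lost methylation at most loci: 27 of 32 tested fell in plasma cells (28 adjusted over the list alone) and 14 in plasmablasts (16 adjusted over the list alone). Of all 14220 loci 9638 fell in plasma cells and 3707 in plasmablasts, the base for the counts of this list and those below. Pax5 ended at 42.5% ± 3.97, Bach2, a repressor of plasma cell genes, fell from 62.9% ± 8.50 to 34.5% ± 6.88 over 59 CpGs (unweighted 61.4% to 45.9%), and Ebf1, a factor of early B cell commitment, fell from 64.3% ± 6.04 to 39.4% ± 7.58 over 43 CpGs. Ikzf3, a lymphoid zinc finger factor, fell from 61.1% ± 3.65 to 28.7% ± 2.29 over 42 CpGs, and Irf8 and Tcf4 fell as well (adjusted p = 0.000139 and 4.57e-05). Cr2, a complement receptor, was at 64.2% ± 3.97, 60.1% ± 5.29 and 52.6% ± 5.57 in the 3 groups and was not called in plasma cells (adjusted p = 0.01), but was with unweighted means in limma, chosen after seeing the data (adjusted p = 5.87e-05). In plasmablasts 31 of the 32 genes had at least 1 fallen CpG, against 23.1 in random lists of like CpG number (adjusted p = 0.0084, random lists). In plasma cells it was 31 against 27.5 (adjusted p = 0.294), and between plasma cells and plasmablasts 6 against 4.46 (adjusted p = 0.684).

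Plasma cell program genes fell at 18 of 23 tested loci in plasma cells (19 adjusted over the list alone) and at 6 in plasmablasts (6 adjusted over the list alone). Besides Irf4 and Prdm1, Sdc1, which encodes the sorting marker CD138, fell from 65.5% ± 8.63 to 36.0% ± 6.00 over 16 CpGs, and Txndc5, a protein folding enzyme, fell from 79.6% ± 1.35 to 51.4% ± 5.45 over 49 CpGs. Xbp1, the transcription factor of the secretory program, fell from 26.7% ± 0.943 to 12.3% ± 5.36 over 7 CpGs (adjusted p = 0.00648), but lost its call without any 1 of naive B cells 2 or 3, plasmablasts 3 or plasma cells 2 or 3 (adjusted p 0.0115 to 0.038) and with the library set as a term (adjusted p = 0.0445). Cxcr4, the chemokine receptor that draws plasma cells to bone marrow, fell from 86.0% ± 3.36 to 64.7% ± 4.80, and the apoptosis gene Bcl2l11 fell from 56.2% ± 3.01 to 40.7% ± 6.32.

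Genes of the response through TLR4 and NF-kB, the pathway that LPS engages, fell at 22 of 28 loci in plasma cells and 14 in plasmablasts, with the same counts adjusted over the list alone. Il10 ended at 8.93% ± 3.22, Traf1 fell from 54.5% ± 3.03 to 24.2% ± 5.01, Nfkbia, an inhibitor of NF-kB, fell from 81.8% ± 4.52 to 50.6% ± 8.82 (unweighted 75.8% to 57.0%), and Cd180, a TLR4-like receptor, fell from 88.4% ± 1.25 to 71.3% ± 2.91. Genes of the unfolded protein response and secretion fell at 28 of 39 loci in plasma cells (28 adjusted over the list alone) and 5 in plasmablasts (3 adjusted over the list alone). Among them Sel1l, part of the machinery that removes misfolded proteins, fell from 85.2% ± 4.55 to 56.3% ± 3.36 (unweighted 92.5% to 74.6%), Sec61b, a subunit of the protein translocation channel, fell from 75.3% ± 3.53 to 53.4% ± 4.80, and Lman1 and Sec31a fell too (adjusted p = 0.000181 and 0.00395), the latter not with the library set as a term (adjusted p = 0.0146). Homing and adhesion receptors fell at 12 of 20 loci in plasma cells (12 adjusted over the list alone) and 4 in plasmablasts (3 adjusted over the list alone). S1pr1, which guides lymphocytes out of tissues, fell from 63.3% ± 9.77 to 33.1% ± 3.68, and S1pr2 was at 45.4% ± 11.2 and 30.7% ± 14.2 (adjusted p = 0.0949). The change was called with unweighted means in limma, chosen after seeing the data (adjusted p = 5.62e-06).

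Proliferation genes fell at 12 of 22 loci in plasma cells (11 adjusted over the list alone) and 1 in plasmablasts (1 adjusted over the list alone), with the cell cycle genes Ccnd2, from 37.7% ± 1.34 to 23.9% ± 4.21, and Cdk6, from 72.0% ± 11.0 to 43.2% ± 9.18 (unweighted 68.4% to 49.8%), among those that fell. The call of Cdk6 was lost with the library set as a term (adjusted p = 0.027) and without plasma cells 3 (adjusted p = 0.0112). The DNA methylation machinery fell at 14 of 23 loci in plasma cells (13 adjusted over the list alone) and 6 in plasmablasts (6 adjusted over the list alone). Dnmt1, the maintenance methyltransferase, fell from 94.2% ± 0.452 to 81.7% ± 0.417 over 29 CpGs, and Tet2 ended at 58.5% ± 6.20. Among all genes 9638 of 14220 loci fell in plasma cells and 3707 in plasmablasts, so the counts do not single out either list.

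Marker loci of cell types that the sort should exclude also fell, as did 9638 of all 14220 loci in plasma cells and 3707 in plasmablasts. T cell markers fell at 17 of 19 loci in plasma cells and 9 in plasmablasts (17 and 11 adjusted over the list alone), for example Tcf7, from 44.1% ± 2.70 to 25.7% ± 6.48 (unweighted 41.4% to 29.6%), and Thy1, from 63.1% ± 11.3 to 35.7% ± 4.58, whose call was lost with the library set as a term (adjusted p = 0.0219). NK cell markers fell at 5 of 6 and 2 loci (5 and 2 adjusted over the list alone), including Eomes, from 39.8% ± 3.39 to 24.1% ± 4.75 (unweighted 39.6% to 29.7%). Myeloid markers fell at 10 of 14 and 2 (11 and 2 adjusted over the list alone), including Csf1r, from 88.7% ± 1.29 to 66.9% ± 3.39. Erythroid and stem cell markers fell at 11 of 16 and 2 (11 and 2 adjusted over the list alone), including Kit, from 74.1% ± 2.57 to 56.7% ± 5.81.

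Hox clusters and Polycomb developmental genes, whose loci stood at a median of only 18.6% in naive B cells, lost less than other genes. In plasmablasts 0 of 61 fell by the quasi-binomial test with limma's dispersion, 0 adjusted over the list alone, with a median difference of -0.402 points, and in plasma cells 24 fell (22 adjusted over the list alone) with a median of -5.67 against -15.7 for all loci. Pax2, a kidney and eye development gene, fell from 30% ± 1.07 to 18.7% ± 3.70 over 205 CpGs, and Six3 fell from 47.0% ± 2.99 to 29.7% ± 6.18 (unweighted 47.2% to 37.2%). In camera this list stood above the other genes (adjusted p = 4.1e-08 in plasmablasts and 7.27e-06 in plasma cells, both adjusted p = 0.976 with an estimated correlation), although its medians were below 0. Its mean log2 change in plasmablasts was 0.02 and its median -0.07, so these differ in sign. Restricted to 1000 bp around start sites the difference from other genes was lost (adjusted p = 0.726 and 0.519). The other 13 lists did not pass camera in plasmablasts (adjusted p 0.0698 to 0.950) or plasma cells (adjusted p 0.102 to 0.949), that is, they fell about as other genes did or the test could not tell. Camera works on log ratios, and its direction ran against that of the median in points, set beside all loci, for myeloid markers in plasmablasts and for germline genes and erythroid and stem cell markers in plasma cells.

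**Figure D3:**
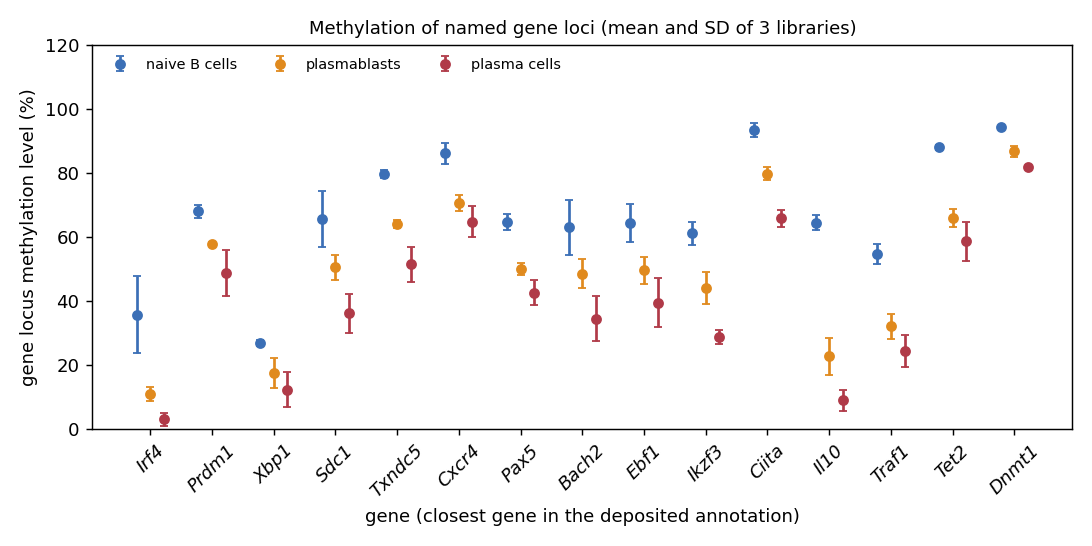
Methylation level (%, y axis) of 15 named gene loci (x axis) in naive B cells, plasmablasts and plasma cells, as the mean of 3 libraries with whiskers of 1 SD. All 15 means step down from naive B cells to plasmablasts and again to plasma cells.

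At Irf4 all 3 fallen CpGs lay in the promoter, while at Prdm1, Pax5 and Il10 most lay in introns or between genes. All or most fallen CpGs assigned to Sel1l, Sec61b, Sec31a, S1pr1, Cd180, Cxcr4, Bcl2l11, Nfkbia, Il10, Tet2, Irf8, Ccnd2, Cdk6, Pim1, Kit and Eomes were intergenic. For such CpGs the gene is only the closest one, at a median distance of up to 412524 bp (Sel1l). The CpG of Irf4 with the strongest change, in its promoter on chromosome 13 at 30839747, -1379 bp from the start site, went from 57.5% ± 11.5 to 8.05% ± 1.81 and 2.42% ± 2.92 (adjusted p = 8.08e-30, coverage 52 to 126 reads per library). That of Prdm1, intergenic on chromosome 10 at 44151723, went from 63.8% ± 7.46 to 14.3% ± 14.3 and 3.11% ± 2.96 (adjusted p = 2.42e-13, 14 to 40 reads). That of Ciita, intronic on chromosome 16 at 10498450, went from 98.3% ± 2.96 to 54.8% ± 9.92 and 11.4% ± 3.57 (adjusted p = 3.01e-25, 16 to 49 reads). Within 1000 bp of their start sites Pax5, Irf8 and Ikzf3 were at 1.35% ± 1.31, 4.52% ± 2.27 and 2.84% ± 3.20 in naive B cells and were not called (adjusted p = 0.796, 0.212 and 0.135). In that window 733 of 7117 genes fell in plasma cells, with Traf1 at 7.47% ± 2.04 and Bach2 going from 28.1% ± 13.2 to 9.29% ± 4.21.

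Neighbouring CpGs fell together in 5985 clusters that held 25.9% of the fallen CpGs. Levels of clusters are means over all tested CpGs inside. The cluster with most called CpGs was in the promoter and exon of Esr1, the oestrogen receptor gene (chromosome 10, 5633884 to 5634377, 17 called of 26 tested CpGs), at 46.3% ± 2.58, 35.2% ± 4.97 and 20.0% ± 0.886 in the 3 groups. In an exon of Cnp, a myelin enzyme gene (chromosome 11, 100437687 to 100438080, 12 CpGs), the levels were 87.2% ± 2.53, 38.4% ± 4.35 and 20.5% ± 8.23. An intergenic cluster on chromosome 14 (54853803 to 54854323, 11 CpGs) went from 78.6% ± 3.38 to 39.3% ± 0.400 and 24.2% ± 5.57. An intron of Heg1 (chromosome 16, 33707806 to 33708352, 11 called of 12 tested CpGs) went from 73.6% ± 5.82 to 33.9% ± 4.57 and 24.6% ± 1.93. The promoter of Mir1905 (chromosome 3, 88340440 to 88340835, 11 called of 15 tested CpGs) went from 60.7% ± 4.33 to 51.3% ± 6.03 and 34.9% ± 4.94.

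Gains were few, and 6 clusters held 13.9% of the 158 risen CpGs. CpGs above 80% in naive B cells could not rise by the minimum difference, and those at 80% or more made up 57.5% of the tested CpGs. In an exon of Egr3, an early growth response factor (chromosome 14, 70479532 to 70479718, 5 CpGs), the levels of naive B cells, plasmablasts and plasma cells were 17.8% ± 6.06, 52.5% ± 1.95 and 47.0% ± 5.10. In an exon of Plscr3 (chromosome 11, 69664578 to 69664771, 4 CpGs) they were 16.5% ± 5.03, 36.3% ± 2.71 and 52.6% ± 5.91, and in an intron of Hif3a (chromosome 7, 17646232 to 17646385, 4 called of 5 tested CpGs) 30.1% ± 1.72, 48.9% ± 6.63 and 57.1% ± 7.40. The Egr3 locus as a whole fell (18 CpGs lower, 5 higher), a call lost with the library set as a term (adjusted p = 0.0261). The loci of Hif3a and Plscr3 as wholes were not called (adjusted p = 0.578 and 0.0868). Anks1 and the cyclin gene Ccnd3 had 3 risen CpGs each and fell as loci, with differences of -13.1 points each (adjusted p = 0.00294 and 0.000747). Unweighted means, chosen after seeing the data, went only from 64.8% to 59.2% and from 45% to 39.2%. Both calls were lost with the library set as a term (adjusted p = 0.0531 and 0.0111). Within 1000 bp of the start site Anks1 was 1.79 points higher (adjusted p = 0.305).

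**Figure D4:**
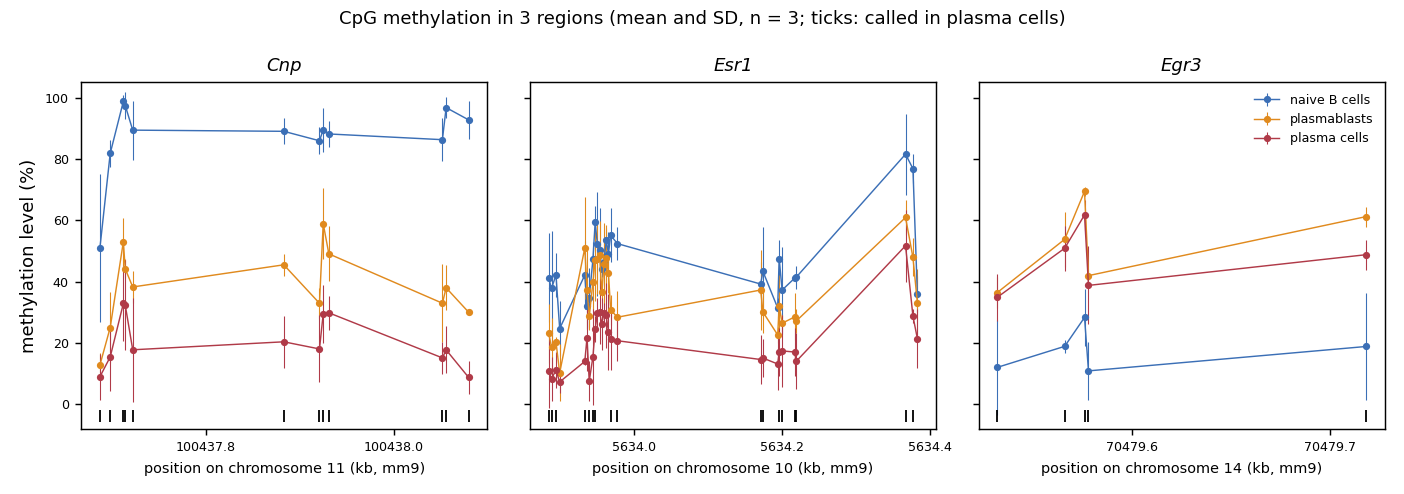
Methylation level (%, y axis) of each tested CpG by position (kb, x axis, mm9) in clusters at Cnp, Esr1 and Egr3, as group means with whiskers of 1 SD (n = 3); black ticks mark CpGs called in plasma cells against naive B cells. At Cnp plasmablasts lie between the other groups at all 12 CpGs, and at Egr3 both LPS groups lie above naive B cells.

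The count of fallen CpGs was 43107 and of fallen loci 5932 with the library set as a term, chosen after seeing the data. The term entered the p-value only, so these are not shown to have fallen by the minimum difference after adjustment for the set. With naive B cells 1, the naive library of the plasma cells' set, as the sole naive library, the mean level differed by -11.2 points. A single library gives no spread for naive B cells. Calls from that fit are therefore listed only among the processing alternatives, and no conclusion is drawn from them. In simulation the set term itself lowered the share of 30-point changes called from 40.3% to 7.46%.

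The third question was what separates plasma cells from plasmablasts. At 2057 CpGs (0.577%) plasma cells were lower and at 3 higher. The lower CpGs averaged 76.1% ± 3.58 in naive B cells, 65.7% ± 2.54 in plasmablasts and 33.6% ± 5.23 in plasma cells (SD, n = 3). The genes with most such CpGs were Gm7120 (11), Arid3a, a DNA-binding factor of B cells (7), and the kinase Cdc42bpb, the survival kinase Pim1 and Rassf3 (6 each). Over whole loci, Arid3a was at 38.4% ± 0.771 and 23.8% ± 5.49, Pim1 at 33.6% ± 3.05 and 19% ± 5.43 (unweighted 33.2% and 24.0%), and Gm7120 at 80.8% ± 1.59 and 69.0% ± 6.00.

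The mean over all CpGs differed by -4.99 points (exact two-sided permutation p = 0.1, the smallest possible), by -4.05 with the library background subtracted and by -10.3 with reads pooled over CpGs. At CpGs of 80% or more in naive B cells plasmablasts stood at 83.0% ± 0.505 and plasma cells at 77.9% ± 2.39. No locus was called: 0 of 14220 fell and 0 rose by the quasi-binomial test with limma's dispersion, with a median difference of -7.78 points. That result depended on plasma cells 1: with this library left out, many loci were called lower. At an unadjusted p under 0.05, 7313 were lower and 1 higher, at an adjusted p under 0.05, 3088 were lower, and with unweighted means in limma, chosen after seeing the data, 1450 fell. Within 1000 bp of start sites 40 genes fell, including Tcf7, a T cell factor, from 63.8% ± 6.88 to 41.0% ± 7.10 (adjusted p = 0.00944). Subtracting the library background left 55.9% of the mean difference within 1 kb of start sites (-3.94 to -2.20 points) and 61.4% of that in promoters. The 3 CpGs that rose, named after their values were seen, were near Gng13 (chromosome 17, 25845348, intergenic, 60.1% ± 8.04 to 92.5% ± 9.13), in an exon of Fam69b (chromosome 2, 26485179, 21.9% ± 4.66 to 51.7% ± 16.5) and in an intron of E130308A19Rik (chromosome 4, 59688194, 14.6% ± 4.69 to 48.3% ± 18.8), with 12 to 53 reads per library.

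The plasma cell program was lower than other genes in this contrast (camera adjusted p = 0.0239, median -10.2 points against -7.78), and 8 of its 23 genes had a fallen CpG against 2.43 in random lists (adjusted p = 0.021). Its camera call was lost with an estimated correlation (adjusted p = 0.976), without plasmablasts 1 (adjusted p = 0.125), with the library background subtracted (adjusted p = 0.0536), with the set as a term (adjusted p = 0.448) and near start sites (adjusted p = 0.684). Of imprinted genes 10 of 30 had a fallen CpG against 4.11 (adjusted p = 0.0448), and the 13 lists besides the plasma cell program did not pass camera (adjusted p 0.0698 to 0.950). Here camera's direction ran against the median in points for the DNA methylation machinery, homing receptors, NK markers and Hox genes. By the quasi-binomial test over all genes 0 members of any list fell at the main threshold. Adjusted over the list alone, 12 mature B cell identity genes, 4 plasma cell program genes, 3 erythroid and stem cell markers, and 1 each of the unfolded protein response, NK and Hox lists fell, and 0 in the other 8 lists.

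This contrast cannot be split within the library sets, since the low set holds no plasmablast library and the high set no plasma cell library. With the set as a term for the p-value, 7 CpGs fell and 0 rose by their unadjusted difference. The count of 2057 also moved with single libraries and with the tool: it was 462, 834, 755 and 490 without plasmablasts 2, plasmablasts 3, plasma cells 2 or plasma cells 3, 3191 without plasma cells 1, 347 by edgeR, 0 by limma and 4336 by Fisher's exact test on pooled counts.

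Most CpGs that fell in plasmablasts also fell in plasma cells, while most of those that fell in plasma cells (48478 of 80488) were not called in plasmablasts. These stood at 88.3% ± 1.34, 74.6% ± 1.01 and 60.5% ± 3.84 in naive B cells, plasmablasts and plasma cells. They were thus lower in plasmablasts too, on average by less than the minimum difference. They were picked with the same naive libraries and by not being called in plasmablasts, so this does not test a graded loss. All CpGs of 80% or more in naive B cells differed by -12.4 points in plasmablasts. Of the 37368 CpGs that fell in plasmablasts 32010 (85.7%) also fell in plasma cells, among them CpGs of Il10 and Traf1, where independent lists would share 8441. Of the risen CpGs 71 were shared, where independent lists would share 0.0998, and 0 CpGs changed in opposite directions. Over all tested CpGs the differences of both contrasts correlated at 0.819 across CpGs, which are not independent replicates. In 20 simulations of unchanged groups sharing a naive group the correlation was 0.472. The covariance of the differences was 113, against 8.05 in the simulations. These redrew all 9 libraries, the naive ones included, from the pooled naive levels with 1 common spread. They hold no real deviations of the naive libraries, so they may understate what shared controls give. With 3 naive libraries the controls could not be split into parts of at least 2 libraries, so part of the excess may come from the shared controls.

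By the authors' deposited calls, 17575 CpGs differed in plasmablasts and 96854 in plasma cells, and 15447 (87.9%) of the former are also among the latter. By their counts 99.8% and 99.9% of them were lower than in naive B cells. Of the 11812 and 54498 that had at least 10 reads in every library, 11811 and 54282 were also called here, and they made up 31.4% and 67.3% of the CpGs called here.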

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

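The tests of bisulfite conversion and of the library set were chosen after the result was seen; the counts of other splits of the samples were planned.

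Reads were found at 23 CpGs of the Y chromosome, although the labels give the mice as female, at 335, 57.9 and 66.3 CPM (reads scaled to equal library totals) in naive B cells 1, 2 and 3, 118, 115 and 146 in plasmablasts 1, 2 and 3, and 313, 326 and 289 in plasma cells 1, 2 and 3. A count of 0 would allow no more than 0.1 to 0.187 CPM. Naive B cells 1 lay with the plasma cell libraries on this measure too. The 23 CpGs together held 10039 reads in naive B cells 1 and 1064 in naive B cells 3. The median CpG of the deposited table held 29 and 14 reads in these libraries. Where the Y chromosome reads come from was not tested, so they do not show male DNA or a wrong label.

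Methylation was lower in plasmablasts and plasma cells than in naive B cells at many CpGs, and incomplete conversion that differs between libraries is argued against as the whole cause: subtracting each library's level at unmethylated CpGs left 97.5% of the difference in mean level between plasma cells and naive B cells. For plasmablasts the background set is argued against as the whole cause, since within the high set the lower of naive B cells 2 and 3 lay 5.97 plasmablast SDs above the highest plasmablast library, but another batch within it stays open: coverage of naive B cells 2 and 3 correlated at 0.908 with each other and at 0.779 at most with a plasmablast library. For plasma cells a batch stays open, since the difference within the low set (-11.2 of -12.6 points, a gap of 5.20 plasma cell SDs) rests on naive B cells 1 alone. The 10 splits of 6 libraries are too few for a share under 0.05; the real split gave 37368 and 80488 fallen CpGs and 3707 and 9638 fallen loci, the highest other split 0 and 4 CpGs and 0 and 0 loci in either direction, and in each case 1 split of 10, the real one, reached the count. Every other split mixes libraries of both groups, so any difference along the real labels, a batch included, lowers its counts. A loss of methylation with differentiation or cell division in LPS-treated mice stays open as a hypothesis, and other differences of the LPS mice, or cells of another type in the sort, were not tested.

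Plasma cells were lower than plasmablasts by a smaller amount. Incomplete conversion is argued against as the whole cause at CpGs of 80% or more in naive B cells, where 95.2% of the difference was left after subtracting the background, but within 1 kb of start sites 55.9% was left, so it stays open there. The library set and the stage cannot be told apart, because no plasmablast library lies in the set of the plasma cells, and with the set as a term 7 CpGs fell, in a model that in simulation had less power. The splits are again too few: the real split gave 2057 lower CpGs, the highest other split, which put plasmablasts 1 with plasma cells 2 and 3, gave 60 in its larger direction, and 1 split of 10 reached the real count. Here too every other split mixes libraries of both groups, which lowers its counts. Later stage, more divisions and library preparation may each contribute.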

How the results depend on the processing

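Chosen after seeing the data were the library set, the subtraction of the library background, coverage per group, each CpG's own spread, the unweighted means and the subsets of naive libraries; the other alternatives were planned. Counts of CpGs or genes are given as lower and higher. In these counts the library set and the replicate block adjusted the p-value only, not the direction or the minimum difference. Counts that rest on a single naive library hold no spread between naive libraries, so no conclusion is drawn from them. The replicates cannot be shown to be separate animals, and plasma cells against plasmablasts cannot be separated from the library set. The replicate numbers gave no sign of pairing: deviations from the group means correlated at -0.0287 to 0.0302 for libraries of equal number and -0.0368 to 0.0419 for the rest. Deviations at single CpGs hold counting error, so these values cannot exclude that libraries share mice. Unless said otherwise the cause of a change was not tested.

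With at least 20 reads per library, the CpG counts were 13136 and 87 in plasmablasts, 27968 and 56 in plasma cells, and 969 and 0 between them; with 30 reads they were 2595 and 31, 5951 and 13, and 200 and 0, from fewer tested CpGs. At an adjusted p under 0.05, 436 CpGs were higher in plasmablasts, and 5772 lower and 18 higher in plasma cells against plasmablasts. Without a minimum difference 72779 and 1084 CpGs were called in plasmablasts, 129486 lower in plasma cells, and 6 higher against plasmablasts. With 30 points the counts were 11444 and 52, 33371 and 52, and 1200 lower in the last contrast. Fisher's exact test called 4336 and 9 CpGs between plasma cells and plasmablasts, edgeR 347 and 0, limma 0 and 0, and the replicate block 711 and 0. CpGs higher than in naive B cells numbered 110 and 98 by edgeR and 98 and 93 by limma, in plasmablasts and plasma cells. With 10 reads per group and at least 1 read in every library (790668 CpGs), 56458 and 503 were called in plasmablasts, 140013 and 269 in plasma cells, and 5 higher in the last contrast. With each CpG's own spread the counts were 22195 and 92, 52328 and 79, and 411 and 0. With the library set as a term, 108 were higher in plasmablasts, 43107 and 84 were called in plasma cells, and 7 and 0 against plasmablasts. With naive B cells 1 alone plasma cells had 40868 and 103, and with naive B cells 2 and 3 alone plasmablasts had 104 higher.

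Leaving out 1 library at a time gave 29243 to 38075 lower and 104 to 300 higher CpGs in plasmablasts (104 without naive B cells 1, 135 without plasmablasts 2), and 65854 to 89454 lower and 110 to 155 higher in plasma cells. Between plasma cells and plasmablasts it gave 462 to 3191 lower (462 without plasmablasts 2, 834 without plasmablasts 3, 3191, 755 and 490 without plasma cells 1, 2 and 3) and 0 to 3 higher (0 without plasmablasts 2, 1 without plasmablasts 1 or 3 or plasma cells 2). Lower genes ranged from 1816 to 4998 in plasmablasts (1816 and 2066 without naive B cells 2 and 3, 1891, 2067 and 2115 without plasmablasts 1, 2 and 3), 6821 to 10585 in plasma cells and 0 to 2978 between them (2978 without plasma cells 1, 4 without naive B cells 1). Higher genes ranged from 0 to 19 in plasmablasts (19 without naive B cells 1, 3 without plasma cells 1) and 0 to 4 in plasma cells (4 without naive B cells 1). The difference in mean level ranged from -8.32 to -7.14, -13.6 to -12 and -5.99 to -4.34 points. Camera called 3 to 5 lists (5 without plasmablasts 3 or plasma cells 1). With reads pooled over CpGs the differences in mean level were -18.9 points for plasma cells against naive B cells and -10.3 against plasmablasts.

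Within 1000 bp of start sites 50 and 0 genes were called in plasmablasts, 733 lower in plasma cells and 40 lower between them; 28 of 46 named genes lost their call there, and Egr3 (2.64 points, adjusted p = 0.272), Anks1 (1.79, adjusted p = 0.305) and Pax2 (0.0122, adjusted p = 0.994) turned upward without a call. With 20 reads the gene counts were 2412 and 4, 5351 and 2, and 1 lower between plasma cells and plasmablasts. The replicate block called 2024 and 0 genes in plasmablasts, the library set 18 higher there and 5932 and 1 in plasma cells, and naive B cells 1 alone 4611 and 1. Unweighted means in limma gave 7998 and 6 in plasmablasts, 2 higher in plasma cells and 1450 lower between them. The library set ended the calls of 10 named genes in plasma cells: Egr3, Anks1, Ccnd3, Sec31a, Cdk6, Thy1, Il2rb, Gzma, Six2 and Xbp1. Camera with an estimated correlation called 0 lists, also near start sites (0, chosen after seeing the data), and fry, which asks whether a list moved at all, 40 of 42. Mature B cell identity was called without plasma cells 1 (adjusted p = 0.0481 and, against plasmablasts, 0.028). Hox genes were called between plasma cells and plasmablasts without plasmablasts 1 or 3 or plasma cells 3 (adjusted p = 0.00644, 0.0457 and 0.0471), and germline genes in plasmablasts without plasmablasts 3 (adjusted p = 0.0457). Of plasmablast losses 89.3% were shared with plasma cells at 20 reads. With gaps of at most 100 bp there were 529, 1651 and 25 clusters of lower CpGs.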

Other observations

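The tests by distance, density and X linkage were planned with their outcomes written down first; the comparison by distance at matched density was chosen after the result was seen.

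Imprinted genes, whose parental copies differ in methylation, fell in plasma cells at 23 of 30 tested loci (25 adjusted over the list alone) and in plasmablasts at 5 (5 adjusted over the list alone). Across all 14220 loci 9638 fell in plasma cells and 3707 in plasmablasts, the base also for the germline genes below. Slc38a4 fell from 93.4% ± 0.0800 in naive B cells to 82.6% ± 0.468 and 78.6% ± 2.26 (SD, n = 3), Dlk1 from 69.1% ± 5.79 to 46.9% ± 4.39 in plasma cells, Nnat from 82.7% ± 4.62 to 65.0% ± 3.72, and Peg13 from 86.0% ± 1.51 to 66.2% ± 6.47. For Dlk1, Nnat and Slc38a4 most of the fallen CpGs were intergenic (20 of 24, 16 of 18 and 17 of 24), and for Peg13 intronic (13 of 15).

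Germline genes, which somatic cells keep silent, were the most methylated list, at a median of 92.7% in naive B cells. They fell at 23 of 32 loci in plasma cells (24 adjusted over the list alone) and 14 in plasmablasts (15 adjusted over the list alone). Piwil2 fell from 93.4% ± 1.10 to 75.1% ± 4.30 and 66.7% ± 4.35, Piwil1 from 89.0% ± 2.64 to 79.9% ± 0.885 and 73.9% ± 2.75, and Dmrtb1 from 83.0% ± 2.81 to 70.6% ± 1.53 in plasma cells, while Tex14 was at 48.6% ± 7 and 37.3% ± 6.33 (adjusted p = 0.0571) but was called with unweighted means in limma, chosen after seeing the data (adjusted p = 4.84e-06). Over whole loci the list did not pass camera, but with CpGs within 1000 bp of start sites it did: its genes were lower than other genes in plasmablasts (adjusted p = 2.04e-07) and plasma cells (adjusted p = 0.0108), and in plasma cells against plasmablasts they lay above the others (adjusted p = 0.0145). All 3 calls were lost near start sites with an estimated correlation, chosen after seeing the data (adjusted p = 0.996).

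Losses were not even among CpGs that started full. At CpGs of 95% or more in naive B cells, those with no more than 1 other CpG of the table within 100 bp dropped by 17.5 points in plasma cells, from 97.9% to 80.4%, and those with 5 or more by 8.53 points, from 98.1% to 89.6%. The loss was larger at the sparse CpGs on 19 of 19 autosomes, as predicted for an effect of the local density of measured CpGs. The CpG density of the genome itself was not measured, and why sparse CpGs lost more was not tested. A larger loss beyond 10 kb from start sites than within 1 kb was seen on 18 of 19 autosomes, but at matched density on 14, 11 and 8 of 19, the last resting on as few as 3 CpGs per autosome, so that distance as such stays open. At these CpGs of 95% or more X linkage is argued against: the X chromosome lost 15.4 points, more than 13 of 19 autosomes and within their range. Over all tested CpGs plasma cells differed from naive B cells by -15.3 points on the X and -12.5 on autosomes. Naive levels differed there too, at 70.7% and 62.2%, and X linkage at CpGs of lower level was not tested.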
